A study of Nicotiana tabacum with 4 samples.

How the data were processed

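Gene expression was measured by RNA sequencing of whole tobacco seedlings (cultivar W38), per the labels' protocols from total RNA taken with Trizol and made into strand-specific libraries with an Agilent kit. The values used are the FPKM (fragments per kilobase of transcript, scaled to library size) that the authors deposited for each gene, in 1 table with 1 column per library. Per the submitters' processing notes, reads passed through bcl2fastq 2.0, TopHat and Cufflinks; the versions of the last of these, the genome build and the count of mapped reads are not given in the sources used here. Per the file headers, the table lists 74273 gene models on RefSeq scaffolds, 61780 with a protein description, and prints 0.0001 for a gene with no fragments, which was so in all 4 libraries for 16234 genes. The raw reads were not used here. The reference table of symbols that came with the series is built on another assembly and was not used, so genes carry the names and scaffold positions of the authors' table, and the sweet potato transgene, which that table does not list, was not analysed here.

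The groups were the 2 genotypes by 2 treatments, 1 library each. Before the data were examined, the groups, the 5 comparisons (H2O2 in W38, H2O2 in IbTLD, genotype untreated, genotype under H2O2, and the difference of the H2O2 differences), the measure, the 47 gene lists, the rule for naming genes and most alternatives were fixed. The measure is the difference of log2(FPKM + 1); expressed genes have a mean FPKM of at least 1 over the 4 libraries (37576), and a gene is called at a log2 difference of at least 1. Each comparison had 1 library a side, and no p-value or standard error was computed; an additive model of genotype and treatment over the 4 libraries would leave 1 residual degree of freedom, the difference of the H2O2 differences itself, and was not fitted. No further scaling was applied: the FPKM sums were 938692, 815133, 848824 and 832611, the medians of expressed genes 5.78, 5.77, 5.78 and 5.76, and 36686, 37625, 37424 and 37446 genes reached FPKM 1, in the order W38 untreated, W38 H2O2, IbTLD untreated, IbTLD H2O2. The 5 genes with the most FPKM held 6.26%, 5.32%, 5.87% and 5.57% of each sum. Across genes the log2 levels of library pairs had correlations from 0.962 to 0.982.

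Lists were keyword rules on the protein descriptions. Each list's median log2 difference was placed among 10000 random lists of the same size, matched on 10 bins of mean level, as a description of these libraries. Members of a list are often copies of each other, and how reads shared by alike copies were divided is not given in the sources used here; 3121 genes share a locus with another gene, which the text states where such a gene is named. Named genes were, per comparison, the 10 largest and 10 smallest differences among genes with a mean FPKM of at least 5 and a description of the product, the 2 largest and 2 smallest of each list, all expressed genes with a TLDc domain, the 5 genes of highest mean, and in the closing section genes of the patterns weighed there; the text gives a choice of these.

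FPKM values of the 4 libraries for a gene are whole multiples of the same step, apart from each library's depth, so numbers of fragments could be recovered. The ratio of the value of 1 fragment to that in W38 untreated was read from the commonest ratio among genes with a mean FPKM under 0.3: 0.892 in W38 H2O2, 0.990 in IbTLD untreated and 0.954 in IbTLD H2O2. A gene counted as whole where its values fitted whole numbers within 0.002 fragment plus a relative 1.2e-05, with at most 400 fragments in its lowest library; 390 solutions whose length would exceed that of the gene were dropped. This held for 21723 expressed genes (57.8%), and for 17457 of 25105 with a mean FPKM of 1 to 10 (69.5%); of 2000 genes whose values were scaled at random by up to 5 percent, 0.0500% passed. From the lengths of 4411 of 17314 genes that lay within 0.4 percent of a common line, depth was estimated at 21.9, 24.6, 22.2 and 23.0 (in units of 1e6 fragments) with a fragment length near 204 bases; these are estimates, not values of the table. Expressed genes under FPKM 10 had a median of 89.0 fragments per library. For these genes the fold has a 95% Clopper-Pearson interval of the fragment numbers, which holds counting error and no variation between seedlings. FPKM and folds are given to 3 significant digits and log2 differences to 2 decimals.

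Alternatives were pseudocounts of 0.1 and 5, no filter, a mean FPKM of at least 5, centring on the median gene, rescaling by a trimmed mean of M values (30 percent of M and 5 percent of A values trimmed on each side), a log2 threshold of 2, and lists without their 3 members of highest level. Added after the data were examined were counts without the genes found almost only in the IbTLD untreated library, counts without plastid and mitochondrial genes, and the correlation of genotype differences. Closing-section tests used thinned fragments (20 draws), bootstraps of list members (2000 draws) and random sets of genes (10000 draws).

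The steps were tested on simulated data: Poisson fragments for 4666 genes at the real means and depths, with 200 genes altered in the W38 H2O2 library. In that simulation of the H2O2 comparison in W38, 10.0% of genes altered 2-fold passed the threshold, 74.0% of those altered 3-fold, 90.0% at 4-fold and 100.0% at 8-fold, and 13 of 4466 unaltered genes passed; in the simulated H2O2 comparison in IbTLD, with no altered gene, 11 of 4666 passed. Most true 2-fold differences among such genes therefore go uncalled. Fragments were recovered up to a common divisor for 97.7% of the simulated genes, so a recovered number can be too small by a whole factor. These genes were ones whose real values had already given whole numbers, which favours a high share. Of the intervals of unaltered genes, 95.4% held 0. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.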

Results

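Tobacco (Nicotiana tabacum) seedlings of cultivar W38 were compared by RNA sequencing in 4 groups: wild type or overexpressing the sweet potato gene IbTLD, each untreated or given 10 mM H2O2 for 6 hours at 12 days of age. Each group was 1 library, so there were no replicates and no replicate check. Every value describes 4 libraries, no p-value was computed, and a difference between genotypes in a response was not tested. Differences are log2(FPKM + 1), a scale that understates the fold of genes with low values. Genes are called higher or lower at a log2 difference of at least 1 among 37576 genes with a mean FPKM of at least 1. The 5 genes with the highest mean level were small subunits of Rubisco, the carbon-fixing enzyme, a glycine-rich protein and a pair of photosystem II 10 kDa polypeptides. In the order W38 untreated, W38 H2O2, IbTLD untreated and IbTLD H2O2, the Rubisco genes stood at 21377, 11876, 17263 and 13078 FPKM (LOC107791770) and at 17608, 13459.7, 15256 and 14062 (LOC107771723). The glycine-rich protein stood at 8595, 9159, 7729 and 9113 (LOC107807593). The photosystem genes stood at 6313, 5064, 5574 and 5849 (LOC107810205) and at 4844, 3773, 3999 and 4240.0 (LOC107816978).

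The transgene itself was not measured, because the table lists tobacco genes and IbTLD comes from sweet potato. Of 8 annotated tobacco genes with a TLDc domain, the domain of the OXR1 family of oxidation resistance proteins, 6 were expressed and none differed 2-fold in any comparison. The OXR1-like genes stood at 16.8, 16.3, 14.7 and 17.2 FPKM (LOC107815720) and at 10.2, 11.2, 9.22 and 9.70 (LOC107813404) in the order given above. The TLD domain-containing protein 1-like genes stood at 18.7, 17.6, 17.4 and 19.7 (LOC107784438) and 5.54, 5.72, 5.99 and 6.11 (LOC107761504). The 2-like genes stood at 2.06, 1.59, 2.03 and 2.69 (LOC107769885) and 2.26, 1.65, 2.05 and 1.69 (LOC107775141).

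In W38, the H2O2 library held 976 genes at least 2-fold higher and 241 at least 2-fold lower than the untreated library, 206 and 26 of them past 4-fold. Small heat shock proteins, which keep unfolding proteins from clumping, were among the largest. A 17.8 kDa class I protein (LOC107779995) stood at 0.0702 FPKM untreated, 1 fragment, and 19.1 with H2O2. A 17.3 kDa class II protein (LOC107796225) stood at 0.109, also 1 fragment, and 16.9. Multiprotein-bridging factor 1c, a transcriptional coactivator of heat and stress responses, stood at 0.157 and 22.4 (LOC107808000, 2 and 321 fragments) and at 0.537 and 22.2 (LOC107787006). The top places also held a family annotated by resemblance as RNA-binding protein 12-like, EspE-like or periaxin-like, with no role in plants given in the sources used here. Its members included LOC107790679 at 19.3 and 447 (log2 difference 4.46), LOC107811710 at 10.4 and 244 (4.43), LOC107811708 at 16.1 and 346 (4.34) and LOC107785438 at 2.56 and 65.7 (4.23). Another of them, LOC107762178, was listed at 0.0001 untreated and at 36.0 with H2O2.

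In W38 with H2O2, of 70 expressed glutathione S-transferases, which join glutathione to reactive compounds, 32 were at least 2-fold higher and none lower (median 0.92). The lead was held by the L3-like LOC107770509 (4.07 and 72.4 FPKM; it overlaps another gene), APIC LOC107779283 (4.36 and 52.1) and PARB LOC107795177 (26.6 and 243). Sulphate assimilation and glutathione synthesis had 11 of 48 members higher and none lower. Among them were ATP sulfurylase 1 LOC107773366 (7.79 and 56.2), 5'-adenylylsulfate reductase 3 LOC107768720 (11.7 and 58.4) and serine acetyltransferase 1 LOC107760267 (4.09 and 17.8). These make the activated sulphate, the sulphite and the cysteine precursor. UDP-glycosyltransferases had 27 of 126 higher and none lower (median 0.28; the 74G1-like LOC107802365 at 1.24 and 18.0). Cytochrome P450s had 12 of 109 higher (94A1-like LOC107812066, 0.711 and 10.1), and ABC and DETOXIFICATION transporters 18 of 196 (ABCG6-like LOC107781832, 1.69 and 12.6; DETOX40-like LOC107810442, 1.84 and 12.4). The transporter list as a whole did not lean either way (median -0.01, or 0.04 with centring or TMM scaling).

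Among enzymes that remove H2O2 and superoxide, few members passed 2-fold, class III peroxidases apart. None of 7 catalases differed 2-fold (isozyme 1-like LOC107828252, 157 and 92.2 FPKM; list median -0.09). In the ascorbate-glutathione cycle 2 of 26 members were higher, both chloroplast glutathione reductases (LOC107777100, 18.1 and 47.3; LOC107777121, 15.1 and 33.7). Of 30 glutathione peroxidases and peroxiredoxins 1 was higher, a phospholipid hydroperoxide glutathione peroxidase (LOC107767209, 76.8 and 159.7; it overlaps another gene). Of 127 thioredoxins and glutaredoxins 2 were higher and 2 lower (glutaredoxin LOC107822846, 58.6 and 159.9; C11-like LOC107827631, 9.62 and 2.53). Superoxide dismutases had 2 of 18 lower and none higher (LOC107806960, 28.0 and 6.82; LOC107767528, 34.8 and 11.4). Among secreted class III peroxidases 17 of 101 were higher and 5 lower, with P7-like LOC107777661 at 1.49 and 16.5 and 5-like LOC107772390 at 7.11 and 0.363. Alternative respiration and NADPH oxidases had 2 of 19 higher, the alternative oxidases LOC107763364 (27.3 and 56.7) and LOC107781761 (22.0 and 51.8), which pass electrons to oxygen without pumping protons.

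Stress regulators differed by family in W38 with H2O2. Heat shock proteins had 43 of 102 higher and none lower (median 0.54; heat shock cognate 70 LOC107802280, 1.21 and 19.1 FPKM). Heat stress transcription factors had 5 of 32 higher (B-3-like LOC107831388, 8.43 and 34.9). ZAT-type zinc fingers, transcription factors of abiotic stress, had 9 of 19 higher (median 0.96; ZAT12-like LOC107767545, 1.67 and 9.49; ZAT10-like LOC107761653, 28.8 and 75.1). WRKY factors of defence had 11 of 84 higher (WRKY40 LOC107801001, 5.27 and 22.2), and ethylene-responsive factors 14 of 129 higher and 1 lower (ERF5-like LOC107802111, 5.01 and 26.8). NAC factors had 3 of 55 higher (NAC2-like LOC107784516, 2.12 and 8.59), MYB 8 of 93 (Myb4-like LOC107810011, 1.40 and 8.68) and bZIP and bHLH 3 of 143 with 1 lower. Calcium signalling had 7 of 173 higher (calmodulin-like LOC107807275, 0.286 and 10.2; CML45 LOC107788983, 2.75 and 20.6). Receptor kinases had 6 of 512 higher.

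Hormone and secondary metabolism lists also differed among themselves. Nicotine synthesis had the largest list median, 1.36, with 6 of 11 members at least 2-fold higher. They included putrescine N-methyltransferases, which commit putrescine to the alkaloid (LOC107771649, 18.8 and 64.3 FPKM; LOC107771646, 11.8 and 34.9), A622 (LOC107784748, 5.90 and 26.3) and nicotinate-nucleotide pyrophosphorylase (LOC107820078, 6.47 and 22.2). Phenylpropanoid and flavonoid synthesis had 21 of 73 higher and none lower (median 0.36). Examples were phenylalanine ammonia-lyase G4-like LOC107831213 (2.60 and 14.1) and caffeoyl-CoA O-methyltransferase 6 LOC107810774 (8.00 and 37.1), enzymes on the way to lignin. Ethylene synthesis had 12 of 43 higher (ACC oxidase-like LOC107759913, 6.91 and 37.3), jasmonate synthesis and JAZ 7 of 43 (12-oxophytodienoate reductase 1-like LOC107766920, 1.22 and 14.6). Proteinase inhibitors had 2 of 29 higher (inhibitor 2-like LOC107792454, 99.9 and 270.4) and pathogenesis-related proteins 8 of 122 with 1 lower (beta-1,3-glucanase 14-like LOC107824944, 7.29 and 28.3). The lipid transfer and epidermis list, with lipid transfer proteins as carriers of cutin and wax precursors, had 30 of 95 higher and 1 lower (LOC107786221, 10.2 and 64.7). Abscisic acid and dehydration genes had 3 of 192 higher and 1 lower (median 0.01).

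Photosynthesis and ribosomal lists lay lower in W38 with H2O2, most members by less than 2-fold. Light harvesting and photosystems had a median of -0.61 over 150 members, with 15 at least 2-fold lower and 1 higher. The list held 15.5% of the summed FPKM untreated and 11.6% with H2O2. Carbon fixation had a median of -0.34 (33 members; small subunit LOC107785215, 2039 and 1010.2 FPKM) and chlorophyll synthesis -0.46 (31 members; glutamyl-tRNA reductase LOC107763283, the regulated entry enzyme, 445 and 232). Cytosolic ribosomal proteins had a median of -0.36 (493 members, none 2-fold lower; S27-2 LOC107784453, 33.2 and 16.9) and organelle-encoded genes -0.37 (69 members, 13 lower and 1 higher, several on fewer than 6 fragments). Auxin response had 14 of 183 lower and 2 higher (median -0.22; 15A-like LOC107783918, 4.89 and 0.935). Cell wall loosening and remodelling had 35 of 275 lower and 15 higher. Extensins, structural wall proteins, went both ways, with 22 of 80 lower (extensin-1-like LOC107806108, 17.5 and 3.30; extensin-2-like LOC107806841, 13.6 and 2.22) and 7 higher (extensin-like LOC107831569, 20.4 and 66.0; extensin-2-like LOC107815826, 8.09 and 27.4). An expansin-like B1 gene stood higher (LOC107794363, 0.676 and 18.6). Among the lowest named genes were kirola-like proteins of the latex protein family (LOC107809756, 16.3 and 0.399; LOC107796413, 76.7 and 9.99) and arabinogalactan protein 19-like LOC107813686 (13.3 and 1.79). Aquaporins had 7 of 59 higher and 1 lower (TIP2-1-like LOC107786005, 421 and 198).

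As a description of these libraries, the W38 medians of the glutathione S-transferase, heat shock, ZAT-type, nicotine, phenylpropanoid, class III peroxidase and WRKY lists lay at percentile 100.0 of 10000 random lists matched on expression. Those of the light harvesting, chlorophyll, ribosomal, organelle, auxin and cell wall lists lay at percentile 0.0. Random lists of like level had medians of -0.18 for light harvesting and -0.15 for ribosomal proteins, so part of these shifts was shared by genes of that level. Where whole fragments could be recovered, the counting interval of the fold lay clear of no difference for 784 of 803 genes called higher and 146 of 171 called lower. That interval holds counting error only. Here and in the other comparisons the genes were called on these same fragments. Most intervals of called genes are therefore clear by that choice, and their number is no independent support. The counts depend on the pseudocount (1561 higher and 537 lower with 0.1, 390 and 88 with 5) and on the level filter (497 and 146 at a mean FPKM of at least 5). Of the lists outside the central 95% of random lists, 7 with small positive medians turned below 0 with that filter (cytochrome P450s -0.01, alternative respiration -0.07, heat stress factors -0.02, proteinase inhibitors -0.01, ethylene synthesis -0.01, abscisic acid -0.01 and root-associated transport -0.13). Inside it, cyclins and cell division went from 0.03 to -0.06.

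**Figure D1:**
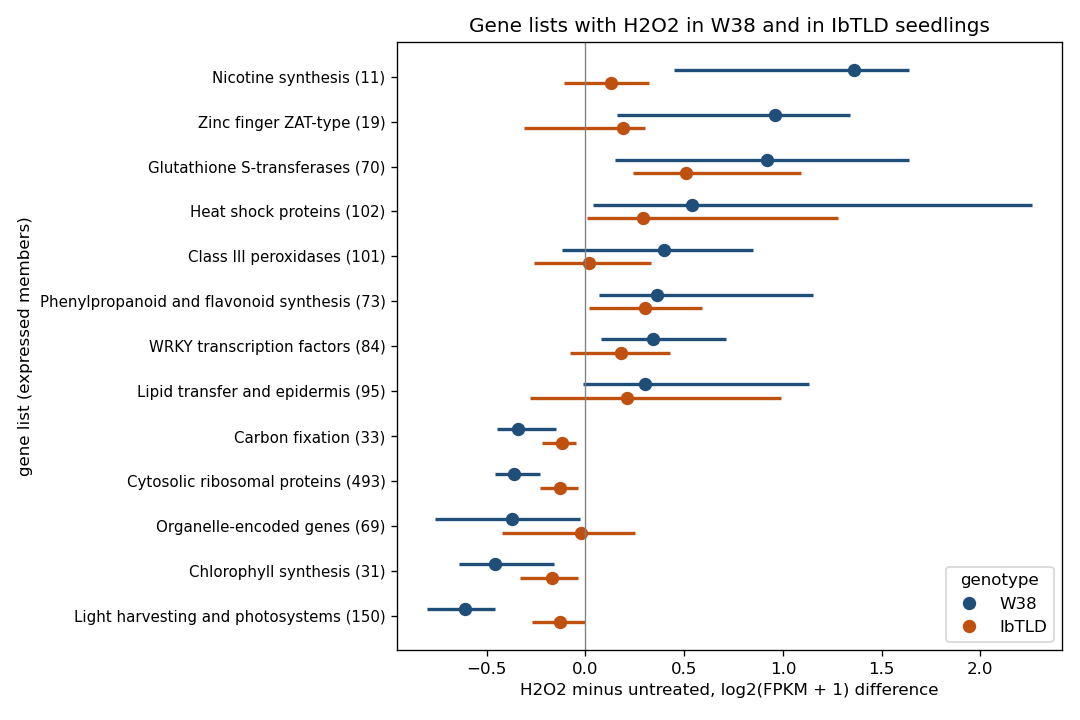
Medians (points) and quartiles (lines) of the log2(FPKM + 1) difference, H2O2 minus untreated, for the gene lists with a median of at least 0.3 either way in either genotype, W38 in blue and IbTLD in orange, with the number of expressed members in brackets. Glutathione S-transferases (0.92 and 0.51) and heat shock proteins (0.54 and 0.29) lay above 0 in both genotypes, while light harvesting lay at -0.61 in W38 and -0.13 in IbTLD.

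In IbTLD seedlings, the H2O2 library held 457 genes at least 2-fold higher and 225 at least 2-fold lower than the untreated library, 72 and 85 of them past 4-fold. Of the 85, 35 were found almost only in the IbTLD untreated library, and 50 remain without them. The largest was a TAS14-like dehydrin gene, of a family that protects cells in drying (LOC107763249), at 0.712 FPKM untreated and 84.3 with H2O2, 12 and 1475 fragments. A related gene, LOC107825693, stood at 30.8 and 156. Small heat shock proteins followed, at 0.0727 and 7.70 (LOC107802502, 1 and 110 fragments) and 0.179 and 8.78 (LOC107813676, 1 and 51 fragments). Next came multiprotein-bridging factor 1c LOC107787006 (0.709 and 11.5), the stress-associated zinc finger protein LOC107829941 (1.34 and 16.4), app1-like LOC107773253 (21.9 and 156) and periaxin-like LOC107785438 (1.90 and 26.4). A metallothionein type 3 gene, of small metal-binding proteins, stood at 7.98 and 56.6 (LOC107826987). An 11 kDa late embryogenesis abundant protein stood at 0.201, 2 fragments, and 15.2 (LOC107777457), and expansin-like B1 LOC107790386 at 6.49 and 36.6.

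Several lists had members higher here too. Heat shock proteins had 34 of 102 higher and none lower (median 0.29). Glutathione S-transferases had 20 of 70 higher and none lower (0.51; PARB LOC107795177, 25.5 and 101 FPKM; APIC LOC107779283, 3.18 and 21.5). Sulphur and glutathione synthesis had 8 of 48 higher (0.19; ATP sulfurylase LOC107773366, 8.44 and 35.8; 5'-adenylylsulfate reductase LOC107768720, 15.3 and 57.4) and UDP-glycosyltransferases 12 of 126 with 1 lower (0.16; LOC107802365, 1.71 and 8.91). The lipid transfer and epidermis list had 24 of 95 higher and 14 lower (0.21, or 0.45 without the 13 found almost only in IbTLD untreated, which are among the 14). In it LOC107807546 stood at 51.5 and 227 and LOC107796974 at 16.8 and 91.0. Ethylene synthesis had 5 of 43 higher and 1 lower (ACC oxidase 3-like LOC107788083, 22.4 and 63.6) and phenylpropanoid synthesis 4 of 73 (0.30; caffeoyl-CoA O-methyltransferase 3 LOC107789328, 10.8 and 23.8). Pathogenesis-related proteins had 4 of 122 higher with 1 lower (osmotin-like LOC107787812, 58.3 and 145), and thioredoxins and glutaredoxins 3 of 127 with 1 lower (C9-like LOC107800971, 2.07 and 5.83). Heat stress factors had 2 of 32 higher (LOC107831388, 8.54 and 24.6). WRKY factors had 2 of 84 higher and 1 lower (WRKY45 LOC107815437, 0.391 and 1.88) and ethylene-responsive factors 2 of 129 higher and 3 lower (ERF2-like LOC107797398, 4.70 and 15.9).

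Several lists had no or few members past 2-fold in IbTLD. None of 11 nicotine genes (median 0.13), 19 ZAT-type zinc fingers (0.19, or -0.09 without the 3 members of highest level), 7 catalases (-0.09) or 18 superoxide dismutases (0.02) differed 2-fold. The superoxide dismutase LOC107806960 stood at 10.6 and 5.71 FPKM and the putrescine N-methyltransferase LOC107771649 at 33.0 and 28.4. Light harvesting had a median of -0.13 with 2 of 150 lower and 1 higher, ribosomal proteins -0.13, chlorophyll synthesis -0.17 and carbon fixation -0.12. Cell wall genes, by contrast, had 35 of 275 lower and 6 higher (median -0.23). Of 80 extensins 26 were lower and 1 higher, with LOC107806108 at 24.7 and 1.26, LOC107806841 at 17.1 and 0.737 and LOC107794667 at 11.8 and 0.642. Class III peroxidases had 4 of 101 higher and 7 lower (44-like LOC107797731, 8.91 and 0.370). The kirola-like genes stood at 54.4 and 7.15 (LOC107796413) and 8.05 and 0.427 (LOC107809756).

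Of the 225 genes lower with H2O2 in IbTLD, 35 were found almost only in the IbTLD untreated library. Among them were 13 lipid-transfer proteins (LOC107810708 at 44.3 FPKM and LOC107812012 at 25.3, both listed at 0.0001 in the other 3 libraries), 3 vignain-like proteases and a phospholipase A1-like gene (LOC107778251, 18.6 FPKM against 0.703 at most elsewhere). Their FPKM summed to 589 there and to 13.0 at most in another library. Without them 190 genes were lower. As a description of these libraries, the heat shock, glutathione S-transferase, sulphur and phenylpropanoid medians lay at percentile 100.0 of the random lists and the cell wall, light harvesting and ribosomal medians at 0.0. Counting intervals lay clear of no difference for 348 of 367 genes called higher and 159 of 180 called lower. A pseudocount of 0.1 or 5 gave 866 or 161 higher and 441 or 92 lower.

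**Figure D2:**
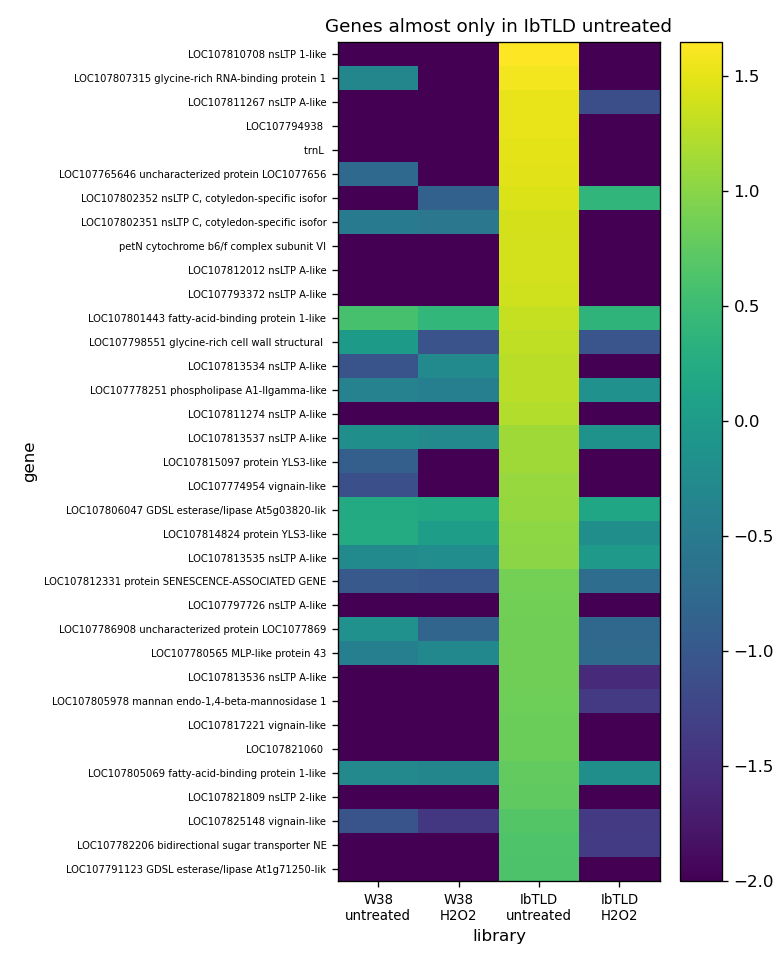
FPKM on a log10 colour scale of the 35 genes whose log2 level in the IbTLD untreated library was at least 2 above each other library, 1 line per gene and 1 column per library. Lipid-transfer proteins (13 of 35) form the largest group, and the summed FPKM of the 35 genes was 589 in that library and at most 13.0 in the others.

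Set side by side, the responses of the genotypes overlapped, and most genes higher in both had the larger difference in W38. There were 329 genes at least 2-fold higher with H2O2 in both genotypes, against 11.9 for independent lists (976 x 457 / 37576), and 75 lower in both, against 1.44. Across genes the 2 differences, which share no library, had a Pearson correlation of 0.54. The 329 genes higher in both had a median of 2.03 in W38 and 1.43 in IbTLD, and 283 of them had the larger difference in W38. Of the W38 genes called higher, 882 of 976 were also above 0 in IbTLD, where their median was 0.75 against 1.43 in W38; the 457 genes called higher in IbTLD had medians of 1.32 there and 1.62 in W38. Of the 75 genes lower in both, 21 had the larger difference in W38, and their medians were -1.52 in W38 and -2.13 in IbTLD.

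The difference of the 2 differences (IbTLD minus W38) was at least 1 below 0 for 602 genes and at least 1 above 0 for 196. Below 0 stood ZAT12-like LOC107767545 (1.97 in W38 and -0.21 in IbTLD), putrescine N-methyltransferase LOC107771649 (1.72 and -0.21), glutathione S-transferase U9-like LOC107775363 (1.33 and -0.28), and extensin-like LOC107831569 (1.65 and -0.88). So did extensin-2-like LOC107815826 (1.64 and -0.44), xylem cysteine proteinase 1-like LOC107786350 (1.56 and -0.25), peroxidase 66-like LOC107784462 (1.23 and -0.48), calcium-binding protein CML19 LOC107828445 (1.32 and -0.18) and RNA-binding protein 12-like LOC107762177 (3.81 and 0.73). By list, 8 of 19 ZAT-type, 5 of 11 nicotine, 19 of 102 heat shock, 15 of 101 class III peroxidase, 21 of 95 lipid transfer, 27 of 275 cell wall and 11 of 129 ethylene-responsive members were at least 1 below 0. Of the 21 lipid transfer genes, 13 are among those found almost only in IbTLD untreated, and 8 remain without them. Above 0 stood TAS14-like LOC107763249 (1.94 and 5.64), lipid-transfer protein LOC107807546 (-0.06 and 2.12), metallothionein LOC107826987 (1.21 and 2.68), arabinogalactan peptide 20-like LOC107776922 (-1.48 and 0.12), and the abscisic acid receptors LOC107816583 (-1.13 and 0.43) and LOC107776401 (-0.99 and 0.19). So did the superoxide dismutases LOC107806960 (-1.89 and -0.79) and LOC107767528 (-1.53 and -0.46). Between genotypes the superoxide dismutase list had a median of -0.25 untreated and -0.01 under H2O2, so its gap lay in the untreated libraries. Light harvesting had a list median of 0.50, against 0.16 for random lists, with 5 of 150 members at least 1 above 0 and 3 below (LOC107819449, -0.82 and 0.37). Auxin response had 0.17, with 16 of 183 above and 2 below. The correlation moved to 0.62 at a mean FPKM of at least 5, and the counts to 1193 below and 538 above with a pseudocount of 0.1.

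**Figure D3:**
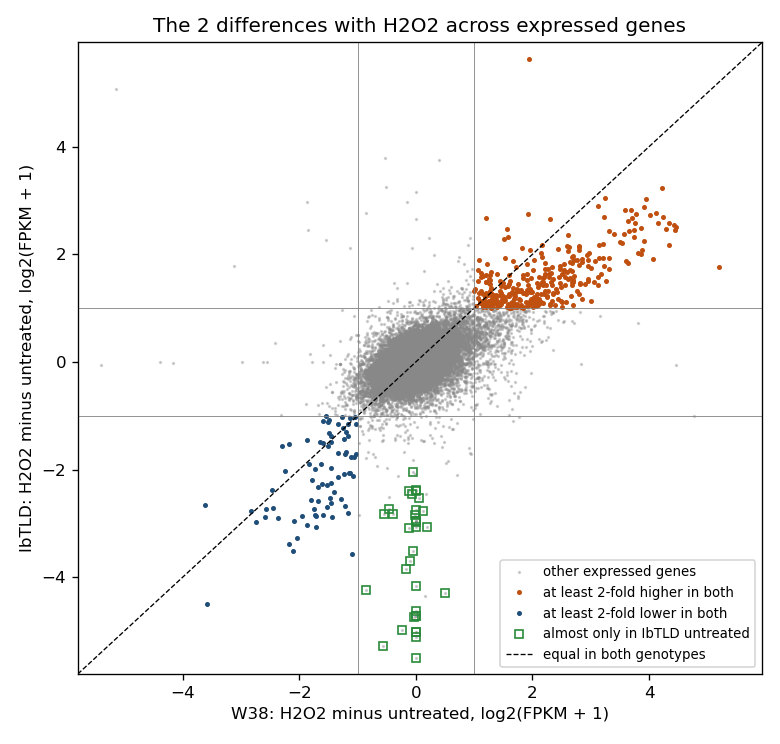
Log2(FPKM + 1) difference with H2O2 in W38 (horizontal) and in IbTLD (vertical), 1 point per expressed gene (37576), with lines at 1 and -1, the diagonal of equal differences dashed, genes past 1 in both coloured and the 35 genes found almost only in IbTLD untreated boxed. The genes higher in both (329) lie mostly under the diagonal, toward W38.

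Between untreated genotypes, 176 genes were at least 2-fold higher and 129 at least 2-fold lower in IbTLD than in W38, 62 and 30 past 4-fold. Of the expressed genes, 94.6% lay within 0.5. Endochitinase A, an enzyme that cuts chitin, stood at 767 FPKM in IbTLD and 45.9 in W38, 16.7-fold apart (LOC107759005; it overlaps another gene). Some genes of seed maturation were higher. They included the Dc3-like late embryogenesis abundant proteins LOC107782653 (11.2 and 0.681) and LOC107793215 (15.0 and 2.5), vicilin-like LOC107819682 (9.62 and 0.757) and oleosin 5-like, a coat protein of oil bodies, LOC107772031 (2.63 and 0.249, 32 and 3 fragments). Across the seed list, 9 of 46 genes at FPKM 1 or more stood 4-fold above each other library in IbTLD untreated, 6 of them mannan endo-beta-mannosidases. Seed storage had 5 of 13 members higher and none lower (median 0.48, percentile 100.0 of the random lists). Glucan-branching enzyme 1-like, of enzymes that make the branches of starch, stood at 14.9 and 1.04 (LOC107808369, a partial gene model), and lipid-transfer protein LOC107796974 at 16.8 and 4.03. ACC oxidase 1-like genes stood at 4.40 and 0.318 (LOC107765010) and at 3.86 and 0.563 (LOC107790081; it overlaps another gene), and CML19 LOC107828445 at 37.0 and 11.2.

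Lower in untreated IbTLD were phylloplanin, a protein that tobacco hairs secrete against fungi (LOC107809147, 29.4 FPKM and 141 in W38, 4.79-fold; phylloplanin-like LOC107773083, 22.9 and 71.7) and the GTPase-activating protein AGD11 (LOC107760300, 1.75 and 11.8). Also lower were miraculin-like LOC107804245 (2.54 and 10.5), a glycine-rich wall protein (LOC107818395, 4.32 and 16.3) and the superoxide dismutases LOC107806960 (10.6 and 28.0) and LOC107767528 (15.1 and 34.8). Stress lists had few members past 2-fold. Glutathione S-transferases had 1 of 70 higher (median -0.05). Heat shock proteins (0.08) and WRKY factors (0.13) had none and ethylene-responsive factors (0.13) 1 of 129 higher and 2 lower, with all 3 medians at percentile 100.0 of the random lists. The nicotine list (0.44, percentile 100.0) and ZAT-type zinc fingers (0.24, percentile 99.9) had no member past 2-fold. Superoxide dismutases had a median of -0.25 (17 of 18 below 0, percentile 0.1). Light harvesting had a median of -0.27 (5 of 150 lower, 1 higher), against -0.13 for random lists of like level. Ribosomal proteins had -0.18 against -0.11, and organelle-encoded genes -0.46 against -0.01 (10 of 69 lower, 3 higher). Of the 176 genes higher, 35 are those found almost only in the IbTLD untreated library, 13 of them among the 17 lipid transfer genes called higher, and 141 remain without them. This comparison shares the IbTLD untreated library with the H2O2 comparison in IbTLD and the W38 untreated library with that in W38, so a value off in either library moves both. Counting intervals lay clear of no difference for 117 of 140 genes called higher and 82 of 110 called lower. A pseudocount of 0.1 or 5 gave 486 or 59 higher.

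With H2O2, 129 genes were at least 2-fold higher and 360 at least 2-fold lower in IbTLD than in W38, 21 and 23 past 4-fold. This comparison shares the H2O2 libraries with the H2O2 comparisons in W38 and IbTLD, so a value off in either library moves both. The lower genes included RNA-binding protein 12-like LOC107762177 (6.39 FPKM and 31.8 in W38), extensin-like LOC107831569 (12.8 and 66.0), xylem cysteine proteinase 1-like LOC107786350 (7.37 and 30.1), peroxidase 66-like LOC107784462 (0.971 and 6.60) and peroxidase 27-like LOC107809480 (1.68 and 6.93). Others were ZAT12-like LOC107767545 (2.36 and 9.49) and LOC107806768 (5.12 and 15.0), and beta-1,3-glucanase 14-like LOC107824944 (8.45 and 28.3). Class III peroxidases had 21 of 101 lower and none higher (median -0.36), cell wall genes 19 of 275 lower and 2 higher, and heat shock proteins 12 of 102 lower (-0.12). Lipid transfer had 11 of 95 lower and 8 higher, and ZAT-type zinc fingers 6 of 19 lower (-0.69). Phenylpropanoid synthesis had 5 of 73 lower (-0.24; caffeoyl-CoA O-methyltransferase 5 LOC107770611, 16.9 and 41.1) and nicotine synthesis 1 of 11 (-0.64). A pair of P450s of the 86A1 type, fatty acid hydroxylases that make suberin, stood at 2.48 and 6.35 (LOC107793147) and 2.73 and 6.80 (LOC107762865), and the ABCG6-like transporter LOC107781832 at 4.23 and 12.6.

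Higher in IbTLD with H2O2 were TAS14-like LOC107763249 (84.3 FPKM and 2.83 in W38) and LOC107825693 (156 and 54.4), endochitinase A LOC107759005 (679.5 and 41.5) and lipid-transfer protein LOC107807546 (227 and 42.5). So were the 11 kDa late embryogenesis protein LOC107777457 (15.2 and 0.453), oleosin 5-like LOC107822372 (13.5 and 0.362) and LOC107772031 (6.80 and 0.148, 86 and 2 fragments), and an expansin-like B1 gene (LOC107785272, 6.83 and 0.0507, 126 and 1 fragments). Seed storage had 4 of 13 higher and none lower (median 0.44), and abscisic acid and dehydration 5 of 192 higher. Auxin response had 9 of 183 higher and none lower (0.21; 15A-like LOC107818179, 2.93 and 0.914) and light harvesting a median of 0.21 with 4 of 150 lower. Phylloplanin LOC107809147 stood at 31.6 and 137. Of the genotype differences, 45 genes were higher and 52 lower in both treatments, against 0.604 and 1.24 for independent lists. Across all expressed genes the 2 genotype differences had a correlation of 0.19. Counting intervals lay clear of no difference for 82 of 100 genes called higher and 280 of 301 called lower. A pseudocount of 0.1 or 5 gave 701 or 102 lower and 362 or 28 higher.

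**Figure D4:**
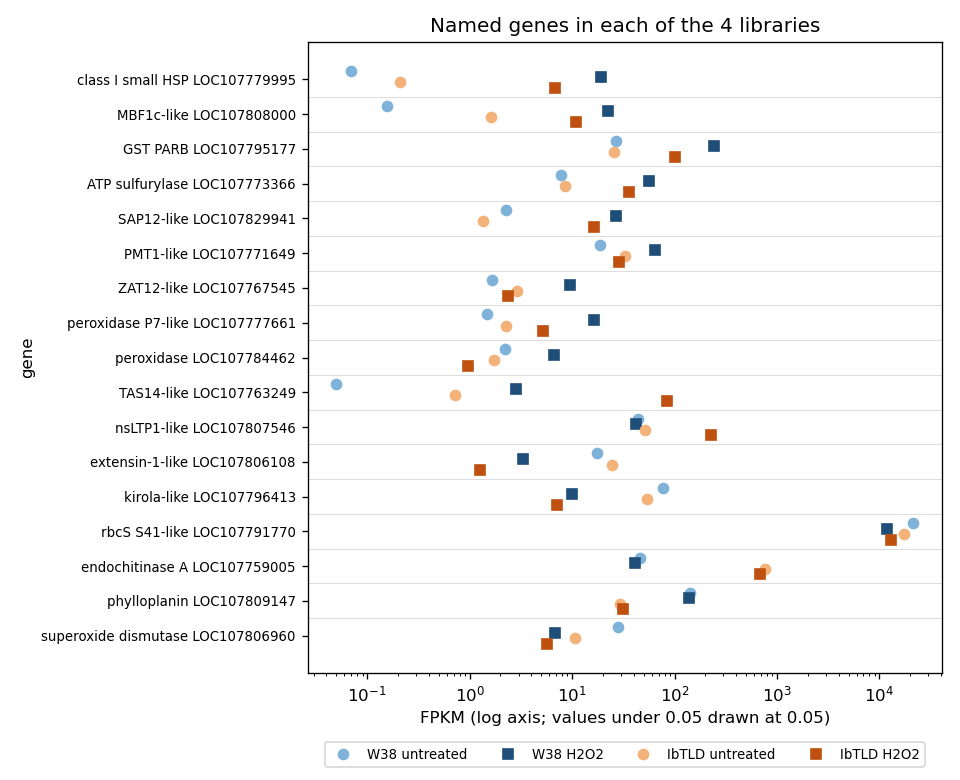
FPKM on a log axis of 17 named genes in each library, circles untreated and squares H2O2, W38 in blue and IbTLD in orange. Endochitinase A and phylloplanin part by genotype, the heat shock and glutathione S-transferase genes and extensin-1-like LOC107806108 part by treatment, and TAS14-like LOC107763249 reached 84.3 FPKM in IbTLD with H2O2 against 2.83 in W38.

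Housekeeping groups gave the scale for small differences. None of 110 subunits of the 26S proteasome, 107 DNA repair genes or 104 histones differed 2-fold in the simple comparisons. Their medians with H2O2 were -0.03, 0.00 and -0.06 in W38 and 0.05, 0.01 and -0.11 in IbTLD. Between genotypes the histone medians were -0.16 untreated (percentile 0.5 of the random lists) and -0.15 with H2O2 (0.0). For the difference of differences the reference genes had 0.18 (percentile 100.0). DNA repair stayed at percentiles 20.7 to 88.7. An extreme percentile with a small median, as given above for some stress lists, thus also occurred in housekeeping groups. Reference genes (actin, tubulin, elongation factor 1-alpha, polyubiquitin) had 2 of 142 higher in W38 with H2O2 (polyubiquitin-like LOC107761578, 4.56 and 13.3 FPKM), with medians of -0.17 in W38 and -0.02 in IbTLD. Cyclins and cell division had 1 of 136 higher in W38, an SMR2-like inhibitor of cell division (LOC107820152, 36.4 and 82.1). Autophagy and senescence had 1 of 78 higher in W38 and 1 lower in IbTLD (1 of the 35 found almost only in IbTLD untreated). Root-associated transport had none of 37 past 2-fold in W38 and 1 each way in IbTLD. Its medians with H2O2 were 0.21 in W38 (percentile 100.0) and 0.12 in IbTLD (99.2), and the W38 median was -0.13 at a mean FPKM of at least 5.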

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

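Of the tests given here, those on anther genes and on thinned fragments were set out before their values were computed, and all others were chosen only after the result was seen. With H2O2, 9 genes lay past a log2 difference of 1 in opposite directions in the genotypes, and the difference between genotypes was not tested. ACC oxidase 1-like LOC107765010, an enzyme of ethylene synthesis, had 8 and 99 fragments in W38 (untreated, H2O2; log2 difference 1.77) and 112 and 44 in IbTLD (-1.02). The plastid genes psbI (-1.87 in W38, 2.98 in IbTLD) and psbM (4.76 and -1.0) rest on 4, 1, 0 and 2 fragments and on 0, 2, 2 and 1. Most of the remaining genes among the 9 also rest on few fragments, such as LOC107772958 on 3, 0, 0 and 1.

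Genes found almost only in the IbTLD untreated library numbered 35, with 13 lipid-transfer proteins, 3 vignain-like proteases and a mannan endo-beta-mannosidase (LOC107805978, 7.04 FPKM there and 0.0421 at most elsewhere). An effect of the transgene alone, whatever the treatment, would have left them high with H2O2. They were chosen as low there, so their fall in IbTLD (summed FPKM 589 and 10.8) tests nothing. A wider set of 47 genes, the 35 included, had a log2 level in IbTLD untreated at least 2 above both W38 libraries. It was chosen with no use of IbTLD H2O2, and 12 of the 47 stayed at least 2-fold above both there. Of the 35, only LOC107802352 was among those that stayed (28.4 FPKM untreated, 2.48 with H2O2, at most 0.137 in W38). The others that stayed lie outside the pattern, so their number could not decide the question for the 35. RNA from anthers, where many lipid-transfer proteins are made, would have brought other anther genes; 0 of 14 expressed anther-list genes stood 4-fold above each other library, but the planned criterion also asked for a list sum no higher than elsewhere and it was 551 against 546, so anthers were not excluded. RNA from seeds or seed coats remains a candidate explanation. With the mannosidases left out as a family already seen, 3 of 32 seed-list genes at FPKM 1 or more stood 4-fold above each other library. Of all genes at FPKM 1 or more there, 0.238% did, a share not matched on level, and all 3 genes lay under 2 FPKM. The summed FPKM of that list was 669 in IbTLD untreated and 495 in IbTLD H2O2. Its members went both ways, with oleosin 5-like LOC107822372 at 1.93 and 13.5 and vicilin-like LOC107819682 at 9.62 and 2.84. A state of those seedlings in which treatment and transgene interact stays open as well, since 1 library per group cannot part it from such material.

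More genes passed 2-fold with H2O2 in W38 than in IbTLD, and deeper sequencing of the W38 H2O2 library did not account for it among the 21723 genes with whole fragments: after thinning all 4 libraries to equal depth the ratio of counts was 1.76 at the lowest of 20 draws, against 1.78 before. Other genes could not be thinned; those with a mean FPKM of at least 5, where depth weighs least, kept a ratio of 1.95 (179 against 92 calls), and the 64 and 43 calls at lower levels were not tested. A weaker exposure in IbTLD that scaled every response alike would leave differences smaller there in both directions. Of the 329 genes higher in both genotypes, 283 had the larger difference in W38, so for them it was not excluded. Of the 75 lower in both, 21 did, with medians of -1.52 in W38 and -2.13 in IbTLD. Those values argue against such scaling for these 75 genes, though 1 library per group gives no spread between seedlings. The gene lists could not decide it. In 9 of 78 pairs of lists the ratios of IbTLD to W38 medians had bootstrap intervals apart, with no allowance for the number of pairs. An example was light harvesting (0.21, 0.11 to 0.25) and cytosolic ribosomal proteins (0.37, 0.32 to 0.43). Members of a list are not independent, and the intervals hold no list-wide shift of a single library. Light harvesting already had a median of -0.27 between untreated genotypes, against -0.13 for random lists. More root tissue in the W38 H2O2 library could be neither shown nor excluded, as the root-associated transport list had a median of 0.02 between the H2O2 libraries (interval -0.29 to 0.15). Only that list was used. Root share behind other lists lower in IbTLD with H2O2, such as nicotine synthesis (median -0.64), was therefore not judged. Nor was a change of root share with H2O2 in W38, where the root-associated transport list had a median of 0.21, or -0.13 at a mean FPKM of at least 5. An effect of IbTLD on the response and a difference between batches of seedlings both stay open, because no group had a second library.

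Genotype differences recurred in both treatments for 45 genes higher and 52 lower in IbTLD. Chance overlap of 2 lists would give 1.24 lower and 0.604 higher, and the lower of the 2 ratios to that was 42.1. Blocks of linked genes that differ between the lines may account for part. Of 94 nuclear genes, 8 shared a scaffold with another of the set, such as AGD11 LOC107760300 with its neighbour LOC107760302, where random sets shared 6 at most. However, 2 of the 8 overlap each other and may share reads. The 8 lie close together on 4 scaffolds, and the random sets were matched on level only. The test therefore cannot tell such blocks from other causes of likeness between neighbours. The other 86 genes were not explained by this test, and noncoding RNAs made up 25 of the 52 lower and 14 of the 45 higher genes against 8.20% of expressed genes. That last share was not matched on level, and the share among all genes called between genotypes is not given here. The contrast may therefore not be particular to the recurrent genes. Whether the transgene, its insertion site or an older difference between the lines lies behind them stays open with 1 transgenic line.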

How the results depend on the processing

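No paired analysis was possible because the labels number no replicates and each group was 1 library, so no library was left out and no test was lost. Alternatives without some genes were chosen only after the results were seen. Counts of genes higher and lower are given in the order H2O2 in W38, H2O2 in IbTLD, genotype untreated, genotype under H2O2, difference of H2O2 differences. With a pseudocount of 0.1 they were 1561 and 537, 866 and 441, 486 and 276, 362 and 701, 538 and 1193, because a smaller pseudocount lets low genes pass by construction. With a pseudocount of 5 they were 390 and 88, 161 and 92, 59 and 35, 28 and 102, 38 and 156. At a mean FPKM of at least 5, with fewer genes by construction, they were 497 and 146, 270 and 96, 58 and 50, 46 and 177, 54 and 269. At a log2 threshold of 2 they were 206 and 26, 72 and 85, 62 and 30, 21 and 23, 24 and 75. Only there did IbTLD have more genes lower than higher with H2O2, and without the 35 genes found almost only in IbTLD untreated 50 of the 85 lower remain. W38 and IbTLD kept their order for higher genes throughout. No filter, centring, TMM scaling and the runs without genes found almost only in IbTLD untreated or without organelle genes left the 10 counts within 1.5 times; the runs without those 35 genes gave 190 lower with H2O2 in IbTLD and 141 higher between untreated genotypes. The correlation of H2O2 differences was 0.60 with a pseudocount of 5, 0.49 with no filter and 0.62 at a mean FPKM of at least 5; the cause was not tested. At a mean FPKM of at least 5 these list medians, none above 0.21 in size in the main setting, changed sign, and the cause was not tested; they are those outside the central 95% of random lists, where MYB untreated also went from 0.05 to -0.00, and 19 medians inside it changed sign too, none above 0.11 in size in the main setting. In W38 with H2O2 they were cytochrome P450s -0.01, alternative respiration -0.07, heat stress factors -0.02, proteinase inhibitors -0.01, ethylene synthesis -0.01, abscisic acid -0.01 and root-associated transport -0.13; in IbTLD with H2O2, jasmonate -0.01. Between genotypes they were sulphur -0.06 untreated, and WRKY 0.01, cyclins 0.01 and receptor kinases 0.02 under H2O2. For the difference of differences they were MYB 0.09 and receptor kinases 0.01. The ZAT-type median in IbTLD was -0.09 without its 3 members of highest level, and -0.00 with no filter. Alternative respiration in W38 was -0.00 without its 3 such members, and lipid transfer between untreated genotypes -0.00 without the 35 genes. With scaling no median outside the central 95% of random lists changed sign, but 15 inside it did with centring and 13 with TMM, none above 0.05 in size before or after. No named gene past a log2 difference of 1 changed sign with another pseudocount or scaling. In the simple comparisons a pseudocount cannot change a sign, and the scaling shifts were too small to reverse such a difference. Over the named genes, the comparisons and these alternatives, 138 results crossed the threshold of 1 and 2582 stayed on the same side. Depth limits genes of low level: of 803 higher calls with whole fragments in W38, the counting interval lay clear of no difference for 784, though they were called on those same fragments.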

Other observations

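No test was run for this part, and the groups described were chosen only after their values were seen. By share of all FPKM, glutathione S-transferases held 0.238% in W38 untreated and 0.611% with H2O2, and 0.259% and 0.438% in IbTLD. Nicotine synthesis genes held 0.0103% and 0.0302% in W38 and 0.0158% and 0.0179% in IbTLD, so that with H2O2 the W38 seedlings had the higher share and untreated the IbTLD seedlings. Phenylpropanoid and flavonoid genes held 0.0904% and 0.165% in W38 and 0.0987% and 0.125% in IbTLD, and aquaporins, the water channels, 1.01% and 0.820%, and 0.943% and 0.768%. Carbon fixation held 5.53% and 4.17% in W38 and 5.11% and 4.36% in IbTLD. Genes of the plastid genome held 0.358%, 0.312%, 0.367% and 0.247% of FPKM in the 4 libraries, in the order W38 untreated, W38 H2O2, IbTLD untreated, IbTLD H2O2. These sums did not follow the typical gene, as the organelle-encoded list had medians with H2O2 of -0.37 in W38 and -0.02 in IbTLD. Transfer RNA genes of all genomes held 0.101%, 0.123%, 0.129% and 0.0418% in the same order, and their part in the plastid sums was not tested.

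The genes higher in IbTLD in both treatments held genes of seed maturation and starch. Of the 45, 5 were late embryogenesis abundant or Em-type proteins, 4 were glucan-branching enzymes and 4 were members of the seed storage list, while none of the 52 lower genes belonged to these groups. Most of the branching enzymes are partial gene models, so they may not be 4 separate genes. A regulator of dehydration responses, ABSCISIC ACID-INSENSITIVE 5-like protein 7 (LOC107767352), stood at 1.31 and 5.38 FPKM in W38 and at 2.06 and 4.33 in IbTLD, untreated and with H2O2. Library-specific genes, with a log2 level at least 2 above each other library, numbered 5 in W38 untreated, 3 in W38 H2O2, 35 in IbTLD untreated and 7 in IbTLD H2O2.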
